A study of Mus musculus with 9 samples.

How the data were processed

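The study followed mouse primary myoblasts, the proliferating precursors of skeletal muscle, through differentiation in culture. Per the labels' protocols, the cells came from skeletal muscle of wild-type Balb/c mice, total RNA was isolated in triplicate with a column kit, labelled with biotin and hybridised to Affymetrix arrays. The labels give 3 time points with 3 arrays each: cycling myoblasts at 0 days, and myotubes after 2 and 5 days in differentiating medium. The sample titles name a differentiating medium for the myotubes, whereas the growth protocol of every sample gives the same medium with serum and growth factor, so the medium of the myotubes is taken here from the titles alone. Nothing in the labels says whether the 3 replicates of a time point came from separate cultures or animals. The p-values of single genes therefore rest only on the spread between these arrays, which may be technical. The processing described below made that spread too small. For gene lists camera compares the members with all other genes, and the permutation p of isoform pairs rests on signs over pairs. No p-value here measures a spread between cultures or animals.

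The deposited values are log2 expression values from the RMA method, which corrects background, brings arrays to one distribution and summarises the probes of a probe set by median polish, and per the submitters' processing notes and design text RMA was run for each replicate set. The version of the software is not given in the sources used here. The values themselves show which arrays were normalized together. The sorted values of any 2 arrays of one time point differed by 0.0251 on average at most, and those of 2 arrays from different time points by at least 0.188. No probe set had the same value, within a tolerance of 1e-06, on arrays of different time points. Within a time point 47.9% of probe sets in cycling myoblasts, 60.2% at day 2 and 56.7% at day 5 had the same value on all 3 arrays. The normalization set was therefore the time point, so normalization set and time point cannot be told apart, and levels at different times were never brought to one scale before deposit.

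The table held 35556 probe sets on 9 arrays, and every column of values was used. The platform annotation named 1 gene for 21789 probe sets, several genes for 1621 and none for 12146. Entrez gene identifiers of 21698 probe sets matched the RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Probe sets that named several genes or none were left out of the gene tests. Of the probe sets naming a gene alone, the one with the highest mean over the 9 arrays stood for the gene, which gave 19938 genes. A gene was tested if that probe set lay above the 30th percentile of its array on at least 3 arrays, which left 16582 genes. Levels of different probe sets served to choose the probe set of a gene, to group genes by level and to match random pairs of genes, and no gene is said here to be expressed above another. The deposited table holds no measure of background, so low levels are not shown to lie above it. How many changes had their lower level at or below the filter value on all 3 arrays was counted after seeing the data. These were 109 of 1002 rises and 137 of 1394 falls at day 2 against cycling myoblasts, 121 of 736 and 214 of 2040 at day 5 against cycling myoblasts, and 14 of 127 and 50 of 609 at day 5 against day 2, each at least 2-fold on both scales described below. Such changes were not measured on both sides, so their exact sizes and their order are not known.

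The comparisons were fixed before the data were examined. One linear model with a mean for each time point was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off) on the values as deposited. Its 3 contrasts were day 2 against cycling myoblasts, day 5 against cycling myoblasts and day 5 against day 2, with a moderated F test for any difference between time points. Adjusted p-values are limma's, Benjamini-Hochberg over all 16582 genes, with a threshold of 0.05. Size was counted at an absolute log2 fold change (log2FC) of at least 1, a 2-fold change. In addition, 27 gene lists with 574 distinct genes were fixed, of which 528 were tested, 33 had no probe set naming them alone and 13 lay below the filter. Lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 81 combinations of list and contrast. An estimated correlation and fry served as alternatives. The sterol biosynthesis list had an estimated correlation of -0.0399, below the preset 0.01, and still did not pass at day 2 with it (camera adjusted p = 0.241). A call lost with an estimated correlation is therefore not read as an effect of correlation between members. The lists cover myogenic transcription factors, satellite cell and Notch pathway genes, inhibitors of myogenic bHLH factors, sarcomere proteins, excitation-contraction coupling, neuromuscular junction, myoblast fusion, dystrophin complex, glycolysis and creatine kinase, oxidative phosphorylation, sterol biosynthesis, DNA replication, mitosis, G1/S genes, cell cycle inhibitors, ribosome biogenesis, IGF and myostatin signalling, atrophy and autophagy, unfolded protein response, interferon response, chromatin regulators and housekeeping genes. A further 5 lists hold markers of fibroblasts, smooth muscle, adipocytes, leukocytes and endothelium.

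Genes named in the text were drawn from those picked by a rule fixed in advance, and not every gene picked is named. Some members of the pairs of muscle and widely expressed forms, under Other observations, are named outside the rule. In each contrast the rule took the 6 largest rises and 6 largest falls among genes past the threshold whose replicates did not overlap. It also took up to 4 members of each list with the largest absolute change, and 12 genes in every contrast. These 12 were Myod1, Myf5, Pax7, Myog, Mef2c, Cdkn1a, Ccnd1, Mki67, Myh3, Ckm, Id1 and Snai1. Cdkn1a had no probe set naming it alone and was not analysed here.

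Because the time points were normalized apart, every comparison is also given on a common scale, on which all 9 arrays were brought to one distribution by quantile normalization over all probe sets. That scaling was listed as an alternative before the data were examined. The count of genes changed at least 2-fold in the same direction on both scales was added after seeing the data, and leads the text beside the count as deposited. In both contrasts of day 5 its rises equalled in number those as deposited, and its falls those on the common scale. The balance of rises and falls on both scales, in lists too, therefore depends on the general shift between the scales and is not itself a result. The words rose and fell are used only for genes that passed on both scales. The common scale moved the median log2FC over all genes from -0.01 to 0.09 for day 2 against cycling myoblasts, from -0.37 to 0.17 for day 5 against cycling myoblasts and from -0.40 to 0.05 for day 5 against day 2.

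The identical values also make the spread between replicates too small: the median residual SD was 0.0150, limma's prior degrees of freedom were 0.324, and 85 genes had no identical values in any time point. A spread floor was added after seeing the data, which raised each gene's residual SD to at least the median of those 85 genes, 0.0763 as deposited and 0.0760 on the common scale, without shrinkage. The fits were tested on simulated data for day 2 against cycling myoblasts, over 16582 genes with 200 changed. The SD of each simulated gene was drawn from those 85 genes and the noise was independent, so no replicate values were identical. The false calls below therefore do not measure the error of the limma fit on the deposited values. At a log2 change of 0.5 the limma fit recovered 71% of 100 genes and at a log2 change of 1 it recovered 94% of 100, with 13 false calls in all. With the spread floor these shares were 51% and 89%, with 1 false call. Median polish was simulated for the same contrast on 2000 probe sets of 25 probes that did not change, with a noise SD of 0.3 per probe and 0.08 per array. Polish on sets of 3 arrays gave identical values in all 3 arrays for 51.1% of probe sets. The limma fit called 1441 of the 2000 changed at an adjusted p under 0.05, and 0 at least 2-fold. Polish on all 9 arrays gave 1.38% identical and 0 false calls. With so little noise a 2-fold difference could hardly arise, and separate background correction and normalization were not simulated. The 0 at least 2-fold therefore does not show that the 2-fold counts are free of error.

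Other alternatives fixed in advance were median centring, no filter, a filter at the 50th percentile, the mean of a gene's probe sets, every probe set by itself, a trended and robust variance model, only the 6 arrays compared, a replicate block, each array left out in turn, and treat against a log2 change of 1. Figures were drawn with matplotlib in Python 3.11.15. For arrays no depth can be given, and the number of arrays, 3 per time point, limits the precision.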

Results

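Gene expression was measured in mouse primary myoblasts as they differentiated into myotubes, the multinucleate fibres that myoblasts form by fusing. The 9 arrays fell into 3 groups of 3: cycling myoblasts at 0 days, myotubes at 2 days and myotubes at 5 days in differentiating medium. The series title names the time course of myogenic differentiation as the subject, so each later time point was compared with cycling myoblasts and the later with the earlier. Values are log2 RMA values, and each change is given as a log2 fold change (log2FC) as deposited and then on the common scale, on which all arrays have one distribution.

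The arrays of a time point were close to each other, with a Pearson r across probe sets of at least 0.990, against 0.902 to 0.967 between time points. Part of this contrast may come from the processing, which summarised the arrays of a time point together and the time points apart. The array median was 4.34 in cycling myoblasts, 4.26 at day 2 and 3.99 at day 5, and the 75th percentile was 6.66, 6.36 and 5.70. Time points had been normalized apart, so a general difference in level between them cannot be told apart from the normalization. Among the 211 genes the naming rule selected, the highest SD over 3 replicates in any time point was 0.275. Many of these SDs were 0, because identical replicate values are frequent in the deposited table. Each change is therefore given on both scales. The words low side mark a change whose lower level was at or below the filter value on all 3 arrays, which was not measured on both sides. The words under median mark one whose lower level was under the array median, which is not shown to lie above background either. In all, 24 of the 89 changes named at day 2, 18 of 79 at day 5 and 10 of 50 between them had a lower level under the array median, so their exact sizes and order are not known. Neither scale measures a change in the total amount of RNA per cell.

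**Figure D1:**
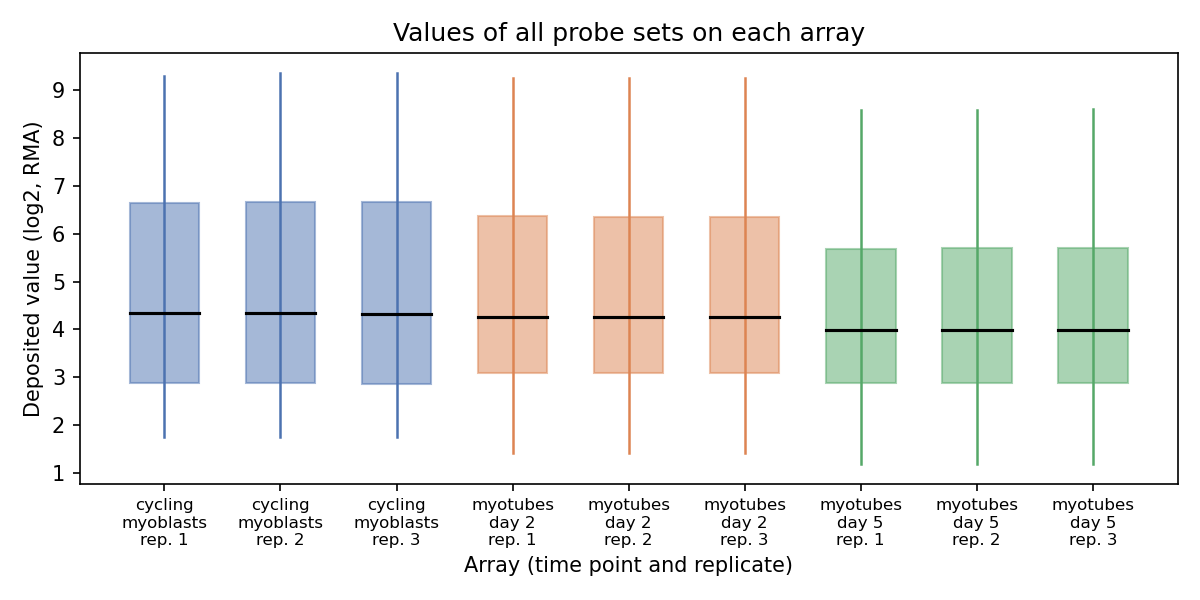
Deposited log2 values of all probe sets on each of the 9 arrays. Boxes span the 25th to 75th percentile with the median as a black line, vertical lines span the 5th to 95th percentile, and the 75th percentile is lowest at day 5, with a mean of 5.70.

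After 2 days the sarcomere list was higher and the mitosis list lower than in cycling myoblasts with camera's preset correlation, and no list passed as deposited with an estimated correlation (adjusted p of at least 0.241). Among the largest measured rises were Fsd2 (low side, log2FC 4.97 and 4.74), the calcium-storing Casq1 (log2FC 4.87 and 5.18) and the muscle creatine kinase Ckm (log2FC 4.83 and 5.12). So were the myosin heavy chains Myh1 (log2FC 4.70 and 5.00) and Myh8 (log2FC 4.67 and 4.97) and the fatty acid transporter Cd36 (under median, log2FC 4.61 and 4.38). Among the largest measured falls were the kinetochore gene Nuf2 (low side, log2FC -6.18 and -6.01), the topoisomerase Top2a (under median, log2FC -6.16 and -5.99) and D17H6S56E-5 (under median, log2FC -5.85 and -5.62). So were Fam111a (low side, log2FC -5.78 and -5.54), the cytokinesis gene Anln (under median, log2FC -5.73 and -5.58) and the spindle checkpoint kinase Bub1 (low side, log2FC -5.61 and -5.37). The largest SD of these genes over 3 replicates was 0.175. On both scales 2396 of 16582 genes changed at least 2-fold, 1002 up and 1394 down. As deposited, 3054 changed at least 2-fold, 1060 up and 1994 down, and on the common scale 2683, with 1281 up and 1402 down. Without the size limit limma called 15477 genes as deposited, 7596 up and 7881 down, and on the common scale 15163, with 8640 up and 6523 down.

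Of the sarcomere list, 40 of 44 measured members rose at least 2-fold at day 2 and 0 fell (camera adjusted p = 1.52e-06, adjusted p = 0.496 with an estimated correlation). Besides Myh1 and Myh8, Mybpc1 (log2FC 4.37 and 4.64), a myosin-binding protein, and Tnnc2 (log2FC 4.17 and 4.45), the fast troponin C, were among them. Embryonic myosin Myh3 was 8.50 ± 0.25 (SD, n = 3) in cycling myoblasts, 11.80 ± 0.0063 at day 2 and 10.64 ± 0.019 at day 5, with log2FC 3.30 and 3.51 at day 2. Of the genes of excitation-contraction coupling, which link membrane depolarisation to calcium release, 16 of 21 rose and 0 fell (camera adjusted p = 0.00125, adjusted p = 0.388 with an estimated correlation). Examples are Hrc (log2FC 4.35 and 4.45), Atp2a1 (log2FC 3.96 and 4.22), the calcium pump of fast fibres, and Trdn (log2FC 3.78 and 4.04). At the neuromuscular junction 5 of 13 rose and 1 fell. Among the rises were Ache (under median, log2FC 3.48 and 3.30), acetylcholinesterase, and Musk (log2FC 1.54 and 1.73). Agrn (log2FC -1.58 and -1.22), agrin, fell. The list as a whole did not pass as deposited (camera adjusted p = 0.0657, and on the common scale upward, adjusted p = 0.0226, adjusted p = 0.154 with an estimated correlation).

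At day 2, 7094 of all 16582 genes were called higher and 6197 lower on both scales at any size. All 17 measured genes of sterol biosynthesis were called higher on both scales at day 2 and 14 rose at least 2-fold (camera adjusted p = 0.000286, adjusted p = 0.241 with an estimated correlation). Msmo1 (log2FC 2.89 and 3.14), Fdps (log2FC 2.85 and 3.09), Cyp51 (log2FC 2.78 and 3.00) and Idi1 (log2FC 2.69 and 2.97) were among the rises. Of oxidative phosphorylation and the TCA cycle, 36 of 37 were called higher on both scales, 7 of them at least 2-fold (camera adjusted p = 0.000149, adjusted p = 0.511 with an estimated correlation). Among the rises there were Cox8b (log2FC 4.15 and 4.44), Cox6a2 (log2FC 3.84 and 4.11) and Cox7a1 (log2FC 3.22 and 3.39), muscle forms of cytochrome c oxidase subunits, and Ndufb8 (log2FC 1.38 and 1.59). Of the genes of glycolysis, glycogen and creatine kinase 11 of 26 rose and 1 fell. The list passed on the common scale alone (camera adjusted p = 0.112, and on the common scale upward, adjusted p = 0.0199, adjusted p = 0.35 with an estimated correlation). Pgam2 (log2FC 3.71 and 4.01), the muscle phosphoglycerate mutase, Ckmt2 (under median, log2FC 3.69 and 3.63) and Slc2a4 (log2FC 3.37 and 3.48), the insulin-responsive glucose transporter, were among the rises besides Ckm.

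All 38 measured mitosis genes fell at least 2-fold by day 2 (camera adjusted p = 2.01e-09, adjusted p = 0.361 with an estimated correlation). Their median log2FC was -4.35 as deposited and -4.10 on the common scale. The proliferation marker Mki67 (low side, log2FC -5.48 and -5.34) was among them. Of 40 DNA replication genes 37 fell and 0 rose (camera adjusted p = 3.32e-07, adjusted p = 0.388 with an estimated correlation). The helicase subunits Mcm6 (under median, log2FC -5.48 and -5.30) and Mcm3 (log2FC -4.49 and -4.25) were among the falls, as were Pole (low side, log2FC -4.14 and -3.89) and Chaf1b (under median, log2FC -4.11 and -3.87). Of the G1/S cyclins, kinases, E2F and Myc genes 10 of 15 fell and 0 rose (camera adjusted p = 0.00931, adjusted p = 0.388 with an estimated correlation). Among them were the cyclins Ccnd1 (log2FC -3.96 and -3.94), Ccne1 (log2FC -3.48 and -3.24) and Ccne2 (under median, log2FC -3.21 and -2.90), and E2f1 (log2FC -2.72 and -2.36). Ribosome biogenesis had 4 of 26 members that fell at least 2-fold and 0 that rose (camera adjusted p = 0.0263, adjusted p = 0.511 with an estimated correlation). These were Utp20 (log2FC -1.83 and -1.58), Srm (log2FC -1.36 and -1.23), Ncl (log2FC -1.26 and -1.14) and Fbl (log2FC -1.15 and -1.02). The cell cycle inhibitors went both ways (camera adjusted p = 0.854). Cdkn1c (log2FC 1.44 and 1.66) and Rb1 (log2FC 1.13 and 1.38) rose, and Rbl1 (log2FC -2.81 and -2.51) and Cdkn2a (log2FC -1.31 and -1.04) fell.

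Among myogenic transcription factors 5 of 14 rose and 3 fell at day 2 (camera adjusted p = 0.984). Mef2c (log2FC 3.60 and 3.89), Myf6 (log2FC 3.04 and 3.09) and Tead4 (log2FC 2.05 and 2.27) rose. Myogenin Myog was 9.15 ± 0.28 (SD, n = 3) in cycling myoblasts, 11.02 ± 0 at day 2 and 9.66 ± 0 at day 5, with log2FC 1.87 and 2.04 at day 2. Myf5 (log2FC -1.55 and -1.43) fell, and Myod1 (log2FC -0.96 and -0.93) was lower by less than 2-fold on both scales. The satellite cell marker Pax7 (log2FC -2.15 and -1.86) fell. So did 8 of 22 satellite cell and Notch pathway genes, Pax7 included, and 1 rose (camera adjusted p = 0.107, and on the common scale downward, adjusted p = 0.000815, adjusted p = 0.0708 with an estimated correlation). Cxcr4 (log2FC -3.70 and -3.48), Vcam1 (log2FC -3.68 and -3.46), Sdc3 (log2FC -3.23 and -2.95) and Fgfr4 (log2FC -2.96 and -2.77) were among the falls. Of the inhibitors of myogenic bHLH factors 6 of 16 fell and 2 rose (camera adjusted p = 0.237, and on the common scale downward, adjusted p = 0.0424, adjusted p = 0.175 with an estimated correlation). Id3 (log2FC -3.37 and -3.18), Id2 (log2FC -3.15 and -3.04), Snai2 (log2FC -3.02 and -2.85) and Id1 (log2FC -2.22 and -2.08) fell. Bhlhe40 (under median, log2FC 3.33 and 3.19) rose, and Snai1 (log2FC -0.95 and -0.61) did not reach 2-fold.

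The remaining lists of muscle and signalling genes did not pass as a whole at day 2. Fusion genes split into 7 that rose and 4 that fell of 25 (camera adjusted p = 0.876). Cav3 (log2FC 4.36 and 4.65), Dysf (log2FC 2.78 and 3.01) and the fusogen Mymk (log2FC 2.36 and 2.57) rose, and Kirrel (log2FC -2.71 and -2.42) fell. In the dystrophin complex 4 of 14 rose and 1 fell (camera adjusted p = 0.679). Dmd (under median, log2FC 3.61 and 3.57), dystrophin, was among the rises, and Sgce (log2FC -1.49 and -1.10) fell. Mstn (log2FC 3.45 and 3.63), myostatin, and its antagonist Fst (log2FC 2.31 and 2.54) rose. Igfbp2 (log2FC -2.60 and -2.37) and Igfbp3 (log2FC -1.41 and -1.28) fell, in an IGF list of which 4 of 17 rose and 2 fell (camera adjusted p = 0.709). The ubiquitin ligase genes Fbxo40 (log2FC 2.65 and 2.79) and Trim63 (log2FC 2.55 and 2.62) rose in the atrophy and autophagy list, of which 4 of 13 rose and 0 fell (camera adjusted p = 0.709). In the interferon and MHC class I list 4 of 15 fell and 0 rose (camera adjusted p = 0.127), with Tap1 (log2FC -3.02 and -2.69) and Psmb8 (under median, log2FC -2.67 and -2.37) among the falls. In the unfolded protein and amino acid response list 1 member rose and 2 fell (camera adjusted p = 0.853), with Casp12 (low side, log2FC -2.42 and -2.16) among the falls. Of the chromatin regulators 2 of 17 rose and 5 fell. Uhrf1 (under median, log2FC -4.69 and -4.50), Hells (under median, log2FC -4.66 and -4.45) and Ezh2 (log2FC -2.57 and -2.42) fell and Hdac9 (under median, log2FC 2.75 and 2.64) rose (camera adjusted p = 0.709).

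By day 5, compared with cycling myoblasts, the sarcomere list was higher and the mitosis list lower with camera's preset correlation, and no list passed as deposited with an estimated correlation (adjusted p of at least 0.241). Among all genes the fast myosin heavy chain Myh4 (under median, log2FC 6.58 as deposited and larger on the common scale), the mitochondrial creatine kinase Ckmt2 (under median, log2FC 5.60 and 6.15) and Cd36 (under median, log2FC 5.39 and 5.81) were among the largest measured rises. The fast myosin-binding protein Mybpc2 (under median, log2FC 5.27 and 5.74), Ankrd23 (log2FC 5.22 and 5.86) and Ckm (log2FC 5.16 and 5.80) were too. The imprinted gene Mest (log2FC -7.20 and -6.64), Top2a (low side, log2FC -6.52 and -6.13) and Anln (low side, log2FC -6.51 and -6.17) were among the largest measured falls, as were D17H6S56E-5 (under median, log2FC -6.32 and -5.86), Kif23 (low side, log2FC -6.20 and -5.85) and Mcm6 (under median, log2FC -6.17 and -5.79). The largest SD of these genes over 3 replicates was 0.109. Myh4 was 3.91 ± 0 (SD, n = 3) in cycling myoblasts, 7.87 ± 0 at day 2 and 10.48 ± 0.0095 at day 5. On both scales 2776 genes changed at least 2-fold, 736 up and 2040 down. As deposited 5576 did, 736 up and 4840 down, whereas on the common scale 4000 did, 1960 up and 2040 down. The excess of falls on both scales thus follows from taking the stricter scale for each direction. Without the size limit limma called 15784 genes as deposited, 4922 up and 10862 down, and 15666 on the common scale, 9339 up and 6327 down. Of these, 3748 genes were called in opposite directions on the 2 scales.

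Of the sarcomere list 38 of 44 genes rose and 0 fell at day 5 (camera adjusted p = 7.39e-10, adjusted p = 0.388 with an estimated correlation). Of excitation-contraction coupling 14 of 21 rose and 0 fell (camera adjusted p = 4.41e-05, adjusted p = 0.388 with an estimated correlation). Among them were Casq1 (log2FC 4.67 and 5.34), Atp2a1 (log2FC 3.97 and 4.55) and the calcium release channel Ryr1 (log2FC 2.69 and 3.56). Glycolysis, glycogen and creatine kinase had 14 of 26 that rose and 1 that fell (camera adjusted p = 0.000226, adjusted p = 0.496 with an estimated correlation). Mb (log2FC 3.76 and 4.23), myoglobin, and Ampd1 (under median, log2FC 3.55 and 4.13) were among the rises besides the creatine kinases. Over all 16582 genes 4921 were called higher and 6326 lower on both scales at any size. For oxidative phosphorylation 34 of 37 were called higher and 2 lower on both scales, with 4 at least 2-fold higher (camera adjusted p = 3.32e-07, adjusted p = 0.388 with an estimated correlation). Cox7a1 (log2FC 4.41 and 5.20), Cox8b (log2FC 4.26 and 5.00) and Cox6a2 (log2FC 3.76 and 4.61) were among these. Cox8a (log2FC -1.15 and -0.36), a widely expressed subunit form, was lower without reaching 2-fold on both scales. Of sterol biosynthesis 7 of 17 rose and 0 fell (camera adjusted p = 0.000758, adjusted p = 0.241 with an estimated correlation), with Fdps (log2FC 1.94 and 2.84) and Msmo1 (log2FC 1.73 and 2.55) among the rises. Embryonic myosin Myh3 (log2FC 2.14 and 2.77) also rose. Atrophy genes Fbxo40 (log2FC 3.65 and 4.44) and Trim63 (log2FC 2.20 and 2.98) rose in a list of which 3 of 13 rose and 0 fell, and which did not pass as deposited (camera adjusted p = 0.679, and on the common scale upward, adjusted p = 0.0251, adjusted p = 0.154 with an estimated correlation). Trib3 (log2FC 1.88 and 2.77) and Herpud1 (log2FC 1.68 and 2.42) rose too in the unfolded protein and amino acid response list, of which 3 of 16 rose and 1 fell (camera adjusted p = 0.519).

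All 38 measured mitosis genes fell at least 2-fold by day 5 (camera adjusted p = 1.26e-05, adjusted p = 0.388 with an estimated correlation), Mki67 (low side, log2FC -5.87 and -5.50) included. Of DNA replication genes 0 of 40 rose and 35 fell (camera adjusted p = 0.000391, adjusted p = 0.496 with an estimated correlation), including Rrm2 (log2FC -5.53 and -4.75) and Mcm4 (log2FC -4.63 and -4.06). Of the G1/S list 0 of 15 rose and 10 fell, with Ccnd1 (log2FC -5.68 and -4.97) among the falls (camera adjusted p = 0.155, and on the common scale downward, adjusted p = 0.000317, adjusted p = 0.123 with an estimated correlation). Of ribosome biogenesis 0 of 26 rose and 13 fell (camera adjusted p = 0.0159, adjusted p = 0.511 with an estimated correlation). Among the falls were Utp20 (log2FC -3.12 and -2.31), Nop58 (log2FC -2.76 and -1.92) and nucleolin, Ncl (log2FC -2.71 and -1.87). The cell cycle inhibitors Rbl1 (log2FC -3.36 and -2.60) and Gadd45g (log2FC -3.08 and -2.23) fell, and 0 members of that list rose (camera adjusted p = 0.679). The chromatin regulators Uhrf1 (low side, log2FC -5.78 and -5.40), Hells (low side, log2FC -5.46 and -5.03), Ezh2 (log2FC -4.04 and -3.18) and Dnmt1 (log2FC -3.07 and -2.23) fell, in a list of which 2 of 17 rose and 7 fell (camera adjusted p = 0.709).

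Pax7 (log2FC -2.91 and -2.08), Myf5 (log2FC -2.39 and -1.55) and Myod1 (log2FC -2.04 and -1.43) fell by day 5. Cxcr4 (log2FC -5.41 and -4.78), Vcam1 (log2FC -5.21 and -4.68), Fgfr4 (log2FC -4.46 and -3.79) and Met (log2FC -4.20 and -3.43) fell among the satellite cell and Notch pathway genes, of which 1 of 22 rose and 10 fell (camera adjusted p = 0.123, and on the common scale downward, adjusted p = 9.36e-05, adjusted p = 0.0708 with an estimated correlation). Snai2 (under median, log2FC -5.51 and -5.03), Id2 (log2FC -4.46 and -3.61), Id3 (log2FC -4.43 and -3.62), Id1 (log2FC -3.63 and -2.82) and Snai1 (log2FC -2.00 and -1.17) fell among the inhibitors of myogenic bHLH factors, of which 1 of 16 rose and 6 fell (camera adjusted p = 0.679, and on the common scale downward, adjusted p = 0.0153, adjusted p = 0.143 with an estimated correlation). Of 14 myogenic factors 3 rose and 5 fell (camera adjusted p = 0.853). Mef2c (log2FC 3.32 and 4.04) and Myf6 (log2FC 4.48 and 5.16) rose, and Tcf12 (log2FC -2.65 and -1.78) and Six4 (log2FC -2.63 and -1.75) fell. Myog (log2FC 0.51 and 1.25) passed 2-fold on the common scale alone. Of 25 fusion genes 9 fell and 4 rose (camera adjusted p = 0.918). Kirrel (log2FC -4.02 and -3.42), Ehd2 (log2FC -3.19 and -2.36) and Myof (log2FC -3.00 and -2.14) were among the falls and Cav3 (log2FC 3.10 and 3.97) among the rises. Igfbp3 (log2FC -3.73 and -2.85), Igfbp2 (log2FC -3.73 and -2.98), Irs1 (log2FC -2.74 and -1.87) and Igf1r (log2FC -2.10 and -1.19) fell in the IGF list, of which 2 of 17 rose and 4 fell (camera adjusted p = 0.709). Tap1 (log2FC -3.37 and -2.66) fell in the interferon list, of which 1 of 15 rose and 3 fell (camera adjusted p = 0.244). Dmd (under median, log2FC 2.11 and 2.80) rose and Sgce (log2FC -2.47 and -1.78) fell in the dystrophin list, the only members past 2-fold (camera adjusted p = 0.709). Ache (under median, log2FC 2.86 and 3.39) rose and Agrn (log2FC -2.20 and -1.33) fell at the neuromuscular junction, where 3 of 13 rose and 1 fell (camera adjusted p = 0.244).

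**Figure D2:**
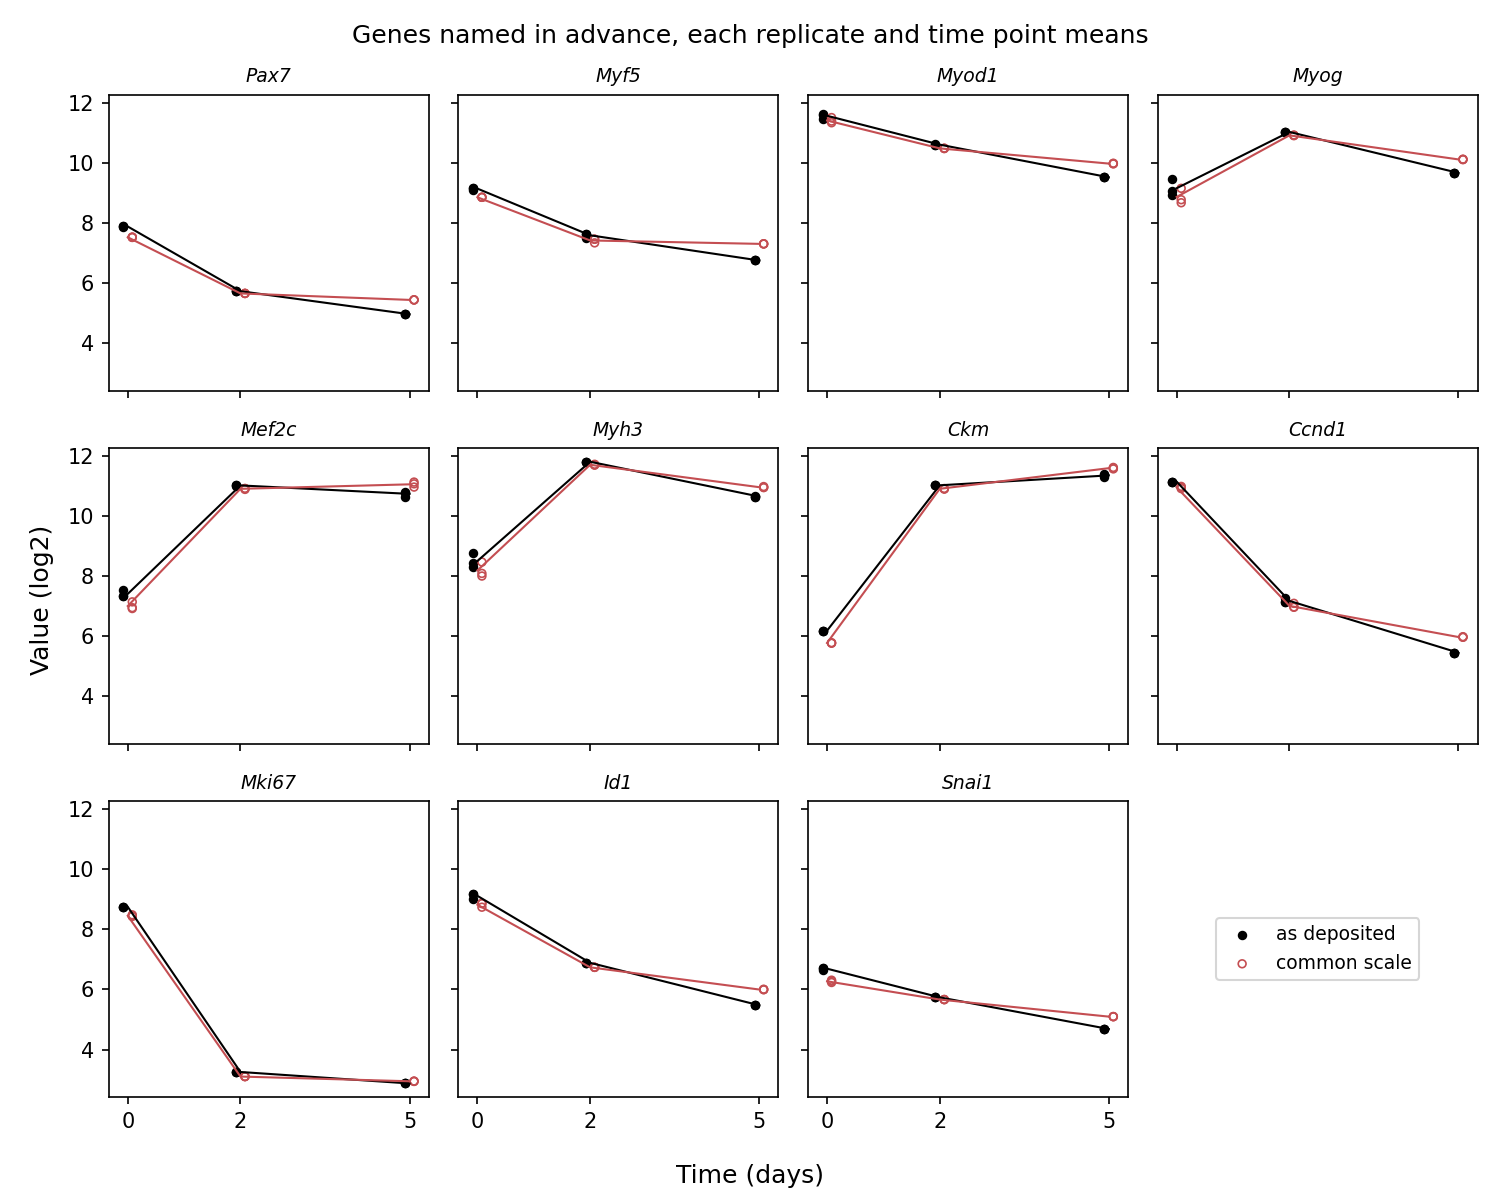
Log2 values over time, in days, of the 11 measured genes named in advance, as deposited (filled) and on the common scale (open), with a point for each of 3 replicates and lines through their means. Mki67 and Ccnd1 fall and Ckm and Mef2c rise by day 2 on both scales, and from day 2 to day 5 Mef2c differs by log2FC -0.28 and 0.15.

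Of the 1002 genes that rose on both scales by day 2, 530 were also at least 2-fold higher than in cycling myoblasts at day 5, 471 were not 2-fold changed on both scales and 1 was 2-fold lower. Of the 471, 278 were at least 2-fold higher on the common scale and 0 as deposited, where 5 were 2-fold lower. Of the 1394 that fell, 1208 were also at least 2-fold lower at day 5, 185 were not 2-fold changed on both scales and 1 was 2-fold higher. Of the 185, 154 were at least 2-fold lower as deposited and 0 on the common scale, where 4 were 2-fold higher. On one scale at a time, 543 of 1060 rises and 1922 of 1994 falls as deposited were shared with day 5, and 984 of 1281 and 1210 of 1402 on the common scale. Both comparisons share the cycling arrays. Independent lists of the same sizes would share 44.5 rises and 171 falls on both scales. As deposited they would share 47 and 582, and on the common scale 151 and 172. Across genes, which are not independent replicates, the log2FCs at day 2 and day 5 had a Pearson r of 0.868 as deposited, against 0.497 in 20 draws of simulated groups with no change against the same arrays. The covariance was 0.931 against a simulated 0.00223. The 3 cycling arrays could not be split into sets of at least 2. They were also normalized as a set of their own, which both comparisons share, so part of the excess may still come from the shared arrays. Another 205 genes rose and 831 fell on both scales at day 5 without having done so by day 2.

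From day 2 to day 5 a smaller set of genes changed on both scales. Among the largest measured rises was phospholamban, an inhibitor of the calcium pump (log2FC 3.94 and 4.50 for Pln). Mybpc2 (log2FC 3.70 and 4.21), Asb11 (log2FC 3.35 and 3.94) and the chemokine Cxcl10 (low side, log2FC 3.12 and 3.78) rose too, as did Ostn (low side, log2FC 2.96 and 3.64), which encodes the secreted peptide musclin, and Fhl1 (log2FC 2.94 and 3.52). Among the largest measured falls were the lysophospholipid transporter Mfsd2a (log2FC -3.56 and -3.16), the probe set annotated to the microRNA gene Mir206 (low side, log2FC -3.48 and -3.28), and the connexin Gjd4 (under median, log2FC -3.26 and -3.02). Tm4sf1 (under median, log2FC -3.08 and -2.81), Dpep1 (log2FC -3.02 and -2.26) and the ribonucleotide reductase subunit Rrm1 (log2FC -2.97 and -2.25) fell too. The largest SD of these genes over 3 replicates was 0.232. On both scales 736 genes changed at least 2-fold, 127 up and 609 down. As deposited 2675 did, 127 up and 2548 down, against 1070 on the common scale, 461 up and 609 down. Without the size limit limma called 15588 genes as deposited, 2679 up and 12909 down, and 15009 on the common scale, 8274 up and 6735 down, with 4699 called in opposite directions. Counts of list members called at any size in this step are to be read against these numbers.

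In this step 5 of 44 sarcomere genes rose and 1 fell, and the list did not pass (camera adjusted p = 0.25). Without the size limit 7 of 44 were called higher and 34 lower as deposited, and 18 higher and 15 lower on the common scale. Myh4 (log2FC 2.61 and 3.13) and Tmod4 (log2FC 2.03 and 2.66) rose, and Myh7 (log2FC -2.08 and -1.40), the slow myosin heavy chain, fell. Of the glycolysis, glycogen and creatine kinase list 5 of 26 rose and 1 fell (camera adjusted p = 0.000817, adjusted p = 0.511 with an estimated correlation). At any size 9 of 26 were called higher and 10 lower as deposited, and 20 higher and 2 lower on the common scale. Ckmt2 (log2FC 1.91 and 2.52), Hk2 (log2FC 1.38 and 2.03) and Mb (log2FC 1.35 and 1.60) rose, and Ckb (log2FC -2.06 and -1.29), the brain-type creatine kinase, fell. The fusion list had 6 of 25 members that fell and 0 that rose (camera adjusted p = 0.715, and on the common scale downward, adjusted p = 0.00736, adjusted p = 0.184 with an estimated correlation). Regardless of size 3 of 25 were called higher and 22 lower as deposited, and 5 higher and 19 lower on the common scale. The fusogen Mymx (log2FC -2.61 and -1.98), Myof (log2FC -2.35 and -1.61) and the cadherins Cdh15 (log2FC -2.31 and -1.56) and Cdh2 (log2FC -2.08 and -1.38) were among the falls. In the unfolded protein and amino acid response list Trib3 (log2FC 1.54 and 2.15) and Casp12 (low side, log2FC 1.39 and 1.93) rose (camera adjusted p = 0.023, adjusted p = 0.511 with an estimated correlation), and 7 of 16 were called higher and 7 lower as deposited, and 14 higher and 0 lower on the common scale. The median of the list was -0.06 as deposited and 0.49 on the common scale. The atrophy and autophagy list also passed upward (camera adjusted p = 0.0141, adjusted p = 0.388 with an estimated correlation), although 0 members rose at least 2-fold on both scales. Of them 6 of 13 were called higher and 5 lower as deposited, and 12 higher and 1 lower on the common scale. Myf6 (log2FC 1.44 and 2.07) rose and Eya4 (log2FC -1.99 and -1.23) fell among myogenic factors, of which 1 of 14 were called higher and 13 lower as deposited, and 3 higher and 10 lower on the common scale (camera adjusted p = 0.709). Mstn (log2FC -1.96 and -1.23), Igfbp3 (log2FC -2.32 and -1.57) and Igf1r (log2FC -1.78 and -1.08) fell in the IGF list, of which 1 of 17 rose and 3 fell (camera adjusted p = 0.407, and on the common scale downward, adjusted p = 0.00387, adjusted p = 0.143 with an estimated correlation). At any size 1 of 17 were called higher and 16 lower as deposited, and 2 higher and 13 lower on the common scale.

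Several lists had few or no members past 2-fold between day 2 and day 5. Over all 16582 genes 2679 were called higher and 12909 lower as deposited, and 8274 higher and 6735 lower on the common scale. With so many genes called, the counts of called members below show little more than direction, to be read against these shares. Cxcr4 (log2FC -1.71 and -1.30), Vcam1 (log2FC -1.53 and -1.22) and Fgfr4 (log2FC -1.49 and -1.02) fell among the satellite cell and Notch genes, of which 0 of 22 rose and 4 fell at least 2-fold. Of the list 0 of 22 were called higher and 22 lower as deposited, and 3 higher and 18 lower on the common scale (camera adjusted p = 0.191, and on the common scale downward, adjusted p = 0.000815, adjusted p = 0.0708 with an estimated correlation). Snai2 (under median, log2FC -2.49 and -2.18) fell among the bHLH inhibitors, of which 1 of 16 were called higher and 13 lower as deposited, and 6 higher and 10 lower on the common scale (camera adjusted p = 0.918). Ect2 (under median, log2FC -2.06 and -1.87) and Kif23 (low side, log2FC -1.17 and -1.01) fell among mitosis genes, of which 5 of 38 were called higher and 31 lower as deposited, and 13 higher and 21 lower on the common scale (camera adjusted p = 0.778). E2f8 (log2FC -2.26 and -1.86), Cdk2 (log2FC -1.84 and -1.13) and Ccnd1 (log2FC -1.72 and -1.03) fell in the G1/S list, of which 1 of 15 were called higher and 12 lower as deposited, and 6 higher and 8 lower on the common scale (camera adjusted p = 0.891). Rb1 (log2FC -1.87 and -1.14) and Gadd45g (log2FC -2.39 and -1.68) fell among the cell cycle inhibitors, of which 2 of 17 were called higher and 15 lower as deposited, and 7 higher and 9 lower on the common scale (camera adjusted p = 0.709). No member of the next 3 lists reached 2-fold on both scales. Of excitation-contraction coupling 1 of 21 were called higher and 17 lower as deposited, and 8 higher and 12 lower on the common scale (camera adjusted p = 0.679), of the neuromuscular junction 1 of 13 were called higher and 12 lower as deposited, and 4 higher and 8 lower on the common scale (camera adjusted p = 0.854) and of the chromatin regulators 0 of 17 were called higher and 16 lower as deposited, and 5 higher and 11 lower on the common scale (camera adjusted p = 0.136). Of DNA replication 4 of 40 were called higher and 33 lower as deposited, and 20 higher and 16 lower on the common scale, and Rrm1 was the one 2-fold lower (camera adjusted p = 0.894). Of sterol biosynthesis 0 of 17 were called higher and 17 lower as deposited, and 2 higher and 15 lower on the common scale, with Lss (log2FC -1.83 and -1.18) at least 2-fold lower (camera adjusted p = 0.115, and on the common scale downward, adjusted p = 0.00204, adjusted p = 0.295 with an estimated correlation). Of ribosome biogenesis 0 of 26 were called higher and 26 lower as deposited, and 2 higher and 22 lower on the common scale, with Nop58 (log2FC -1.93 and -1.19) at least 2-fold lower (camera adjusted p = 0.171, and on the common scale downward, adjusted p = 0.000815, adjusted p = 0.184 with an estimated correlation). Cox7a1 (log2FC 1.19 and 1.81) rose in oxidative phosphorylation, of which 3 of 37 were called higher and 27 lower as deposited, and 33 higher and 2 lower on the common scale (camera adjusted p = 0.679, and on the common scale upward, adjusted p = 0.00501, adjusted p = 0.216 with an estimated correlation). Cxcl10 rose in the interferon list, of which 4 of 15 were called higher and 10 lower as deposited, and 12 higher and 1 lower on the common scale (camera adjusted p = 0.679). Sntb1 (log2FC -2.05 and -1.39) and Utrn (log2FC -1.98 and -1.23), utrophin, fell in the dystrophin list, of which 1 of 14 were called higher and 13 lower as deposited, and 5 higher and 7 lower on the common scale (camera adjusted p = 0.679). Mef2c (log2FC -0.28 and 0.15) had opposite signs on the 2 scales and was not called on the common scale (adjusted p = 0.0584).

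Most lists of markers of other cell types that a muscle culture can hold did not pass. Of the fibroblast and matrix markers 1 of 18 rose and 4 fell by day 2, 0 of 18 rose and 5 fell by day 5 and 0 of 18 rose and 3 fell between days 2 and 5. The rise was Fap (low side, log2FC 1.76 and 1.78). Fn1 (log2FC -4.45 and -3.63), Col3a1 (log2FC -4.15 and -3.41) and Col5a2 (log2FC -2.95 and -2.11) were among the falls by day 5. The list did not pass at day 2 (camera adjusted p = 0.331), at day 5 (camera adjusted p = 0.593) or between them (camera adjusted p = 0.679). Smooth muscle markers did not pass either at day 2 (camera adjusted p = 0.709), at day 5 (camera adjusted p = 0.709) or between them (camera adjusted p = 0.679). Tagln (under median, log2FC -2.81 and -2.21) fell by day 5, and Acta2 (log2FC -1.77 and -1.20) and Tagln (under median, log2FC -1.59 and -1.37) between days 2 and 5. The leukocyte list passed upward at day 5 as deposited only (camera adjusted p = 0.00623, adjusted p = 0.361 with an estimated correlation, and on the common scale adjusted p = 0.197). In it Lyz1 (low side, log2FC 1.10 and 1.19) rose and Laptm5 (log2FC -4.36 and -3.62) fell. At day 2 Itgam (low side, log2FC 1.96 and 1.86) rose and Laptm5 (log2FC -3.05 and -2.87) fell. The list did not pass at day 2 (camera adjusted p = 0.151) or between days 2 and 5 (camera adjusted p = 0.0791). At day 5 the leukocyte median as deposited was 0.255, against 0.266 in the decile of genes with the lowest mean level and -0.37 over all genes. Whether the level of the members accounts for the pass at day 5 was not tested. No adipocyte marker reached 2-fold on both scales in any contrast. The list passed upward between days 2 and 5 (camera adjusted p = 0.00996, adjusted p = 0.361 with an estimated correlation), not at day 2 (camera adjusted p = 0.854) or day 5 (camera adjusted p = 0.523). Between days 2 and 5 its median was -0.07 as deposited, with 4 of 8 called higher and 4 lower. The common scale gave 0.28, with 6 higher and 0 lower. As deposited the median was -0.40 over all genes and -0.09 in the decile with the lowest mean level. The pass as deposited thus means a less negative shift than in other genes, not a rise. No endothelial marker reached 2-fold on both scales, and the list did not pass at day 2 (camera adjusted p = 0.854), at day 5 (camera adjusted p = 0.631) or between them (camera adjusted p = 0.854). Of 9 housekeeping genes, Actb (log2FC -1.31 and -1.55) fell by day 2 (camera adjusted p = 0.575). Actb (log2FC -3.35 and -3.00) and Ywhaz (log2FC -1.69 and -1.05) were lower by day 5 (camera adjusted p = 0.679). Actb (log2FC -2.04 and -1.45) fell further between days 2 and 5 (camera adjusted p = 0.679).

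**Figure D3:**
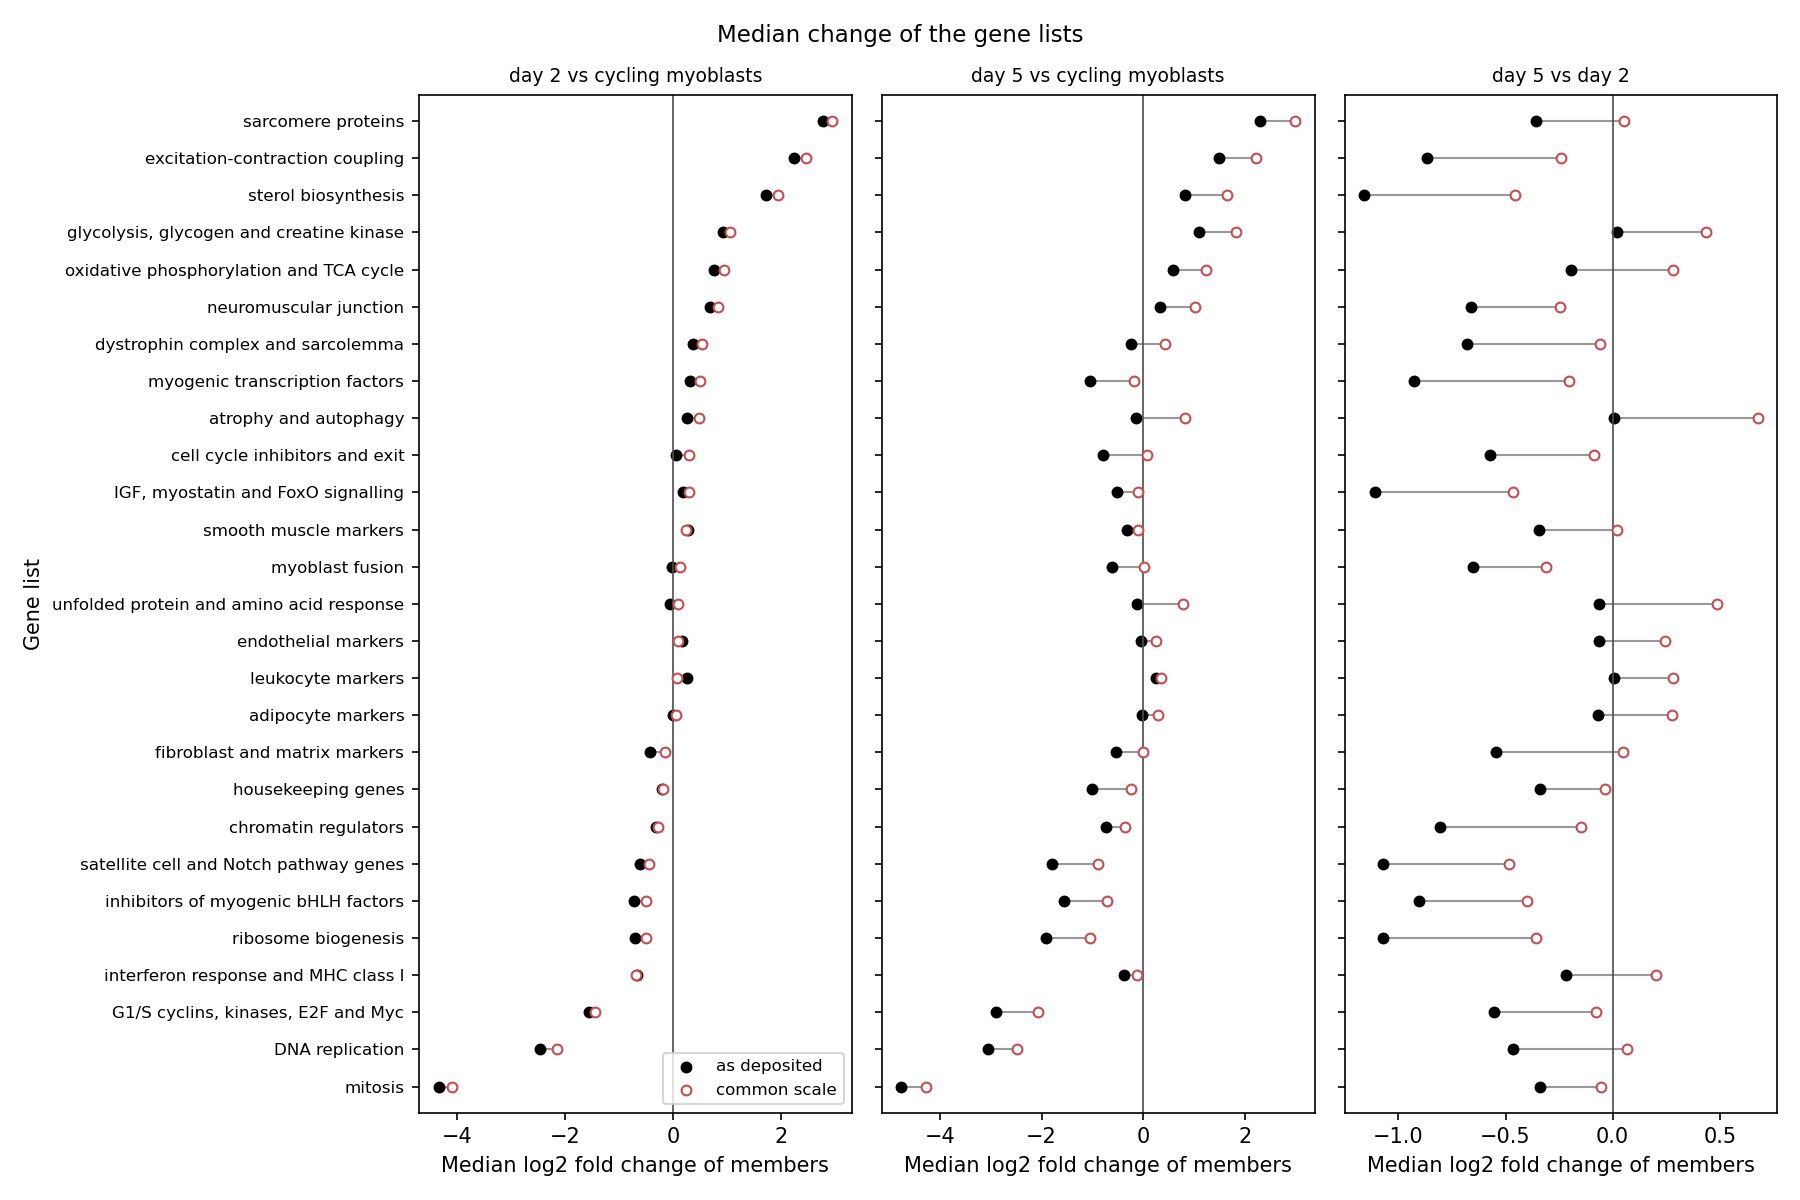
Median log2 fold change of the measured members of 27 gene lists in the 3 contrasts, as deposited (filled) and on the common scale (open). At day 2 sarcomere genes had medians of 2.76 as deposited and 2.94 on the common scale and mitosis genes -4.35 and -4.10, while between days 2 and 5 the sarcomere median changes sign with the scale, from -0.36 to 0.05.

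The F test called 16317 of 16582 genes different between time points as deposited and 16306 on the common scale. Among named genes that changed at least 2-fold on both scales, limma's adjusted p was at most 1.13e-05 at day 2, 1.26e-06 at day 5 and 1.69e-06 between them. Those p-values understate the error because identical replicate values shrink the spread, and with the spread floor on the common scale they were at most 9.39e-05, 1.27e-05 and 0.000159. With the preset correlation 21 of 81 list tests passed as deposited and 34 on the common scale. With an estimated correlation 0 passed as deposited, where 6 had an unadjusted p under 0.05 and fry called 81, in 17 of them in the direction opposite to camera's. Fry's calls rest on the same small spread and are not read as results. On the common scale 2 passed with an estimated correlation, DNA replication at day 2 and at day 5, both at adjusted p = 0.00452. Camera compares a list with all other genes, and in 14 of the 81 combinations the median as deposited had the opposite sign to camera's direction, 2 of them called, the unfolded protein and adipocyte lists between days 2 and 5. Adjusted over the list alone, the same members were called in 81 of 81 combinations of list and contrast as over all genes tested.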

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

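The tests of the general level and of the identical replicate values were chosen only after the results were seen. Probe sets that name no gene were left out of the gene tests, yet their signal changed over time. Of 12146 such probe sets, 7790 lay above the filter on low values. At day 2 against cycling myoblasts 648 of them, 8.32%, changed at least 2-fold on both scales, 143 up and 505 down, against 14.4% of named genes. At day 5 against cycling myoblasts 1428 did, 18.3%, with 114 up and 1314 down, against 16.7% of named genes. At day 5 against day 2 616 did, 7.91%, with 39 up and 577 down, against 4.44%. These shares were not tested against each other. Their balance of rises and falls also depends on the general shift between the scales.

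Most genes were lower at day 5 than in cycling myoblasts in the deposited values, with 10862 of 15784 called genes lower and a median log2FC of -0.374 over all genes tested. On the common scale the median was 0.171. As deposited the shift varied with level, from 0.27 in the decile of genes with the lowest mean to -0.99 in the eighth decile and -0.55 in the highest, against 0.33, -0.02 and 0.21 on the common scale. A fall of most transcripts in myotubes and the separate normalization of the time points cannot be told apart, because each time point was a normalization set of its own and the common scale removes a general shift of either origin. Either may underlie the shift, and both stay open.

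Replicates of a time point shared identical values at 47.9% to 60.2% of probe sets. The highest share identical in any pair of arrays was 67.8%, which argues against a single array given under 2 names, since the remaining probe sets differed. Simulated median polish on sets of 3 arrays gave identical values on all 3 for 51.1% of probe sets, and polish on all 9 arrays for 1.38%, so the identical values are consistent with summarising each time point by itself. The noise in that simulation was set here, not measured. No biological explanation was tested.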

How the results depend on the processing

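The spread floor, its combination with the common scale, the count on both scales and camera on ranks were chosen only after the results were seen. Of 172 comparisons of a count with its value under an alternative, 160 stayed within 1.5 times and 12 moved further. The count of genes changed at least 2-fold between days 2 and 5, 2675 as deposited, was 1070 with quantile normalization, with that and a replicate block, and with that and the spread floor, 1521 with median centring and 736 on both scales. The count at day 5 against cycling myoblasts, 5576 as deposited, was 4000 with quantile normalization and 2776 on both scales. A count on both scales cannot exceed that on either by construction. The cause of the differences between single scales was not tested. Of 81 list tests, 21 passed as deposited, 34 with quantile normalization, alone or with a replicate block or with camera on ranks, and 36 with median centring. With an estimated correlation 0 passed and with fry 81, which tests the genes of a list without comparing them with other genes. In 17 of these 81 combinations fry's direction was opposite to camera's, 1 of them called by camera, the unfolded protein and amino acid response list at day 5 against day 2 (fry adjusted p = 3.11e-18, downward). Fry was upward for the satellite cell and Notch list at day 2 (adjusted p = 2.08e-16) and downward in all others. Yet 17 of the 22 satellite cell and Notch members were called lower as deposited at day 2, with a median log2FC of -0.62. At day 2 these were the myogenic factors (adjusted p = 5.74e-22), dystrophin complex (5.61e-17), glycolysis (4.32e-15), IGF (3.73e-18) and atrophy (4.05e-15) lists. At day 5 against cycling myoblasts they were the myogenic factors (5.29e-23), dystrophin complex (3.83e-21), unfolded protein (2.73e-18), smooth muscle (2.21e-16) and endothelial (7.94e-21) lists. At day 5 against day 2 they were the sarcomere (5.58e-12), oxidative phosphorylation (2.57e-15), interferon (5.01e-23), leukocyte (3.26e-23) and endothelial (1.15e-21) lists. The cause was not tested. Fry rests on the spread between replicates, which identical values made too small, so its p-values and directions are not read as results.

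Of 4358 comparisons of a named gene with an alternative, 4354 kept the direction and side of the threshold, 1 lost the call and 3 turned direction. Those that turned were Mef2c at day 5 against day 2, at a log2FC of 0.15 with quantile normalization, alone, with a replicate block or with the spread floor, against -0.28 as deposited. None of these passed the threshold (adjusted p = 0.0584, 0.0677 and 0.0994). Of 1533 comparisons of a list, 1379 stayed on their side of the threshold, 30 lost the call, 107 gained it and 17 turned, all with fry. Leaving out each array in turn gave 15282 to 15659 genes changed at day 2, 15646 to 15930 at day 5 and 15407 to 15827 between them. At least 2-fold the ranges were 3050 to 3076, 5552 to 5619 and 2641 to 2702, on both scales 2375 to 2406, 2763 to 2785 and 729 to 753, over all time points 16238 to 16370 and for lists 21 to 23. Each left-out array had been normalized and summarised with the others of its time point, so narrow ranges were largely set in advance. The same limit holds for these settings within the comparisons of counts, genes and lists. With the replicate number as a block 15376, 15714 and 15500 genes changed, and it changed no count by over 1.5 times. Deviations from the group mean of same-numbered arrays correlated at -0.0382 to 0.106 over 16582 genes and those of other arrays at -0.151 to 0.163. No pairing by number was seen in these values. They cannot exclude one, because summarising each time point by itself made many replicate values identical and left little deviation to correlate. Signal over background was not used here, so genes near the floor were limited only by the filter.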

Other observations

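Muscle forms of a protein rose against their widely expressed counterparts, in 22 pairs written down after some of the values were known, 12 of which hold a gene named elsewhere. The tests of the 2 scales and of a coordinated switch on these pairs were chosen only after the result was seen. At day 5 against cycling myoblasts the muscle member had the larger log2FC in 22 of 22 pairs on both scales, with a median difference of 4.57 as deposited and 4.44 on the common scale. In 18 pairs the muscle member rose at least 2-fold on both scales and in 8 the widely expressed member fell, while in 1 it rose, Atp2a2 at a log2FC of 1.02 (common scale 1.62). Examples are tropomodulin, with Tmod1 at a log2FC of 3.37 (common scale 4.24) and Tmod3 at -3.76 (common scale -2.98), and filamin, with Flnc at 0.30 (common scale 1.07) and Flna at -6.00 (common scale -5.29). For actin, Acta1 was at 1.29 (common scale 1.64) and Actb at -3.35 (common scale -3.00). At day 2 the median difference was 3.54 as deposited and 3.61 on the common scale, with the muscle member higher in 20 and 21 pairs.

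The permutation p of the mean difference at day 5 was 1e-05 on either scale, the smallest that 100000 resamples can give. A shift shared by all genes cancels in the difference between the members of a pair, so such a shift cannot produce it. For the same reason the median of 4.44 on the common scale was nearly bound to be close to that as deposited. The comparison of scales therefore does not decide whether separate normalization of the time points contributed otherwise. For a lower measured starting level of the muscle members, 10000 draws of random gene pairs matched on level in cycling myoblasts gave medians of at most 2.16. Random pairs with such starting levels thus did not reach the observed median. The 22 pairs were not drawn at random but composed after some of the values were known. Neither the draws nor the permutation p can therefore decide whether the starting level contributed. A coordinated switch of isoforms, with the muscle member ahead in 100% of pairs, may underlie the pattern, and it stays open because the pairs were composed after some of the values were known.

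Other splits of the same arrays were counted, a test planned before the results were seen, and counted on simulated probe sets only afterwards. In each contrast 1 of the 10 splits of 6 arrays into 3 and 3, the real one, gave as many genes, and the highest of the other splits gave 0. Real counts were 15477, 15784 and 15588 genes changed, and 3054, 5576 and 2675 changed at least 2-fold. With 10 splits no share under 0.05 can be reached. For any change over time 1 of 100 drawn splits of the 9 arrays, the real one with 16317 genes, reached that count and the highest other gave 7995. Summarising each time point by itself gives that outcome without any change in expression. Of 2000 simulated probe sets that did not change, polished in sets of 3 arrays, the real split called 1733 and the highest of the other splits 583. These splits therefore do not decide whether chance can be excluded.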
